A study of Homo sapiens with 12 samples.

How the data were processed

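RNA from HEK293T cells was measured on 12 Affymetrix expression arrays, 3 for each of 3 MED26 siRNAs and 3 for a non-targeting control. Per the labels' protocols, cells received 25 nM siRNA, RNA was taken after 48 hours, and biotinylated cRNA was made from 300 ng of total RNA. The labels name more than 1 non-targeting siRNA over the control arrays, while the protocol names only 1, and the control arrays were used as 1 group as the titles give it. The deposited values are probe set intensity values on a linear scale, made with RMA in affy 1.24.2 per the submitters' processing notes. RMA corrects the background, quantile-normalizes the arrays and summarises the probes of a probe set, so the arrays were already on 1 scale, and a change in total RNA per cell cannot be seen. The values ran from 4.36 to 33219. A log2 scale had been assumed before the data were examined, and since the deposited intensity values are linear, log2 was taken here without a pseudocount.

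Of 54675 probe sets, 62 are control probe sets, 41091 name 1 gene, 1801 name several and 11721 are unnamed in the platform annotation used here. The Entrez ID of 41037 one-gene probe sets was found in the RefSeq gene table, which changed 0 symbols. The 19775 genes tested were each represented by the probe set with the highest mean over all 12 arrays, and 10523 had several. Among the 2637 of these called in the mean of the 3 siRNAs, 122 had probe sets called in opposite directions. No dim probe set was left out. HSPA1A was to be named whatever its value, but its probe sets name several genes and it is not reported.

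A model with 4 group means was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes, 8 residual degrees of freedom), with a contrast for each siRNA, for the mean of the 3 siRNAs, and an F test between siRNAs. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes. The 25 gene lists were tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. A list member matched through an older symbol was accepted only where the listed symbol is not a current symbol of another gene, a rule added after a ribosomal protein had been matched to another gene. MED26 was also tested by an exact permutation test over 220 splits. Correlations and overlaps between siRNAs were set beside 100 simulations of unchanged groups with shared controls. On simulated data for the mean of the 3 siRNAs over 19775 genes, 91.0% of log2 changes of 0.5 were called, with 100% of changes of 1 and of 2, and 12 of 206 calls were false.

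The design, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule names MED26 and MYC, the 12 largest mean changes in each direction among genes called with all 3 siRNAs, the 4 largest in each direction with each siRNA, the 6 with the largest range between siRNAs among genes called by the F test, and up to 4 called members of each list. LOC and open reading frame names were passed over. The alternatives were 2 further scalings, a filter on the dimmest 40% of genes, the mean of all probe sets of a gene, other variance models, array weights, the replicate number as a block, stricter thresholds, all probe sets, smaller sets of arrays, and each array left out. A block for replicate 1 against replicates 2 and 3, a fit on replicates 2 and 3, and replicate 1 values alone were added after seeing the data. The reason was that the replicate 1 arrays correlated with each other across groups (0.326 to 0.439, deviations from group means) and not with the rest (-0.391 to -0.0539). Deviations within a group cancel out, so negative values with the rest follow from the positive ones and are no separate evidence. The estimated correlation for list contrasts between siRNAs was also added afterwards. Arrays give no read depth.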

Results

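The series asked which genes respond when MED26 is depleted in HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen. MED26 is a subunit of Mediator, the complex that connects transcription factors to RNA polymerase II. Cells were transfected with 25 nM of 1 of 3 siRNAs against MED26 (s18074, s18075 or s18076) or of non-targeting control siRNA, and total RNA was taken after 48 hours. The labels name more than 1 non-targeting siRNA over the control arrays and the protocol only 1, so the control arrays may differ in it. Each of the 4 groups held 3 Affymetrix arrays, 12 in all. The arrays had median intensities between 72.3 and 73.8, and their number limits the precision of every value given here. The labels number the replicates without saying that they were separate cultures, so the p-values measure the spread between these arrays, which may be technical. Fold changes are differences of mean log2 intensity, knockdown minus control, with the standard error of the limma model. For the mean of the 3 siRNAs, the error and the p-value treat these siRNAs as fixed. They measure the spread between arrays of a group and leave out the spread between siRNAs.

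MED26 itself was lower with every siRNA. On its brightest probe set the control arrays averaged 9.85 ± 0.02 (SD, n = 3, log2 intensity), and the signal fell by 1.10 ± 0.07 (SE) with s18074, by 0.57 ± 0.07 with s18075 and by 1.08 ± 0.07 with s18076. These changes left 46.6%, 67.5% and 47.3% of the control signal. Over the mean of the 3 siRNAs MED26 fell by 0.92 ± 0.06, and the exact two-sided permutation test of the 9 knockdown arrays against the 3 controls gave p = 0.00455, the smallest that its 220 splits allow. MED26 stayed higher with s18075 than with s18074 by 0.54 ± 0.06 (limma, Benjamini-Hochberg adjusted p = 0.000256), and it was lower with s18076 than with s18075 by a log2 difference of -0.51 ± 0.06 (adjusted p = 0.000224). Both other MED26 probe sets were dim and did not pass the test with any siRNA. The first of them, at 6.22 ± 0.21 in the controls (SD, n = 3), gave log2 fold changes of -0.27, 0.30 and -0.30, and the second, at 5.38 ± 0.47, gave 0.33, 0.13 and 0.18.

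**Figure D1:**
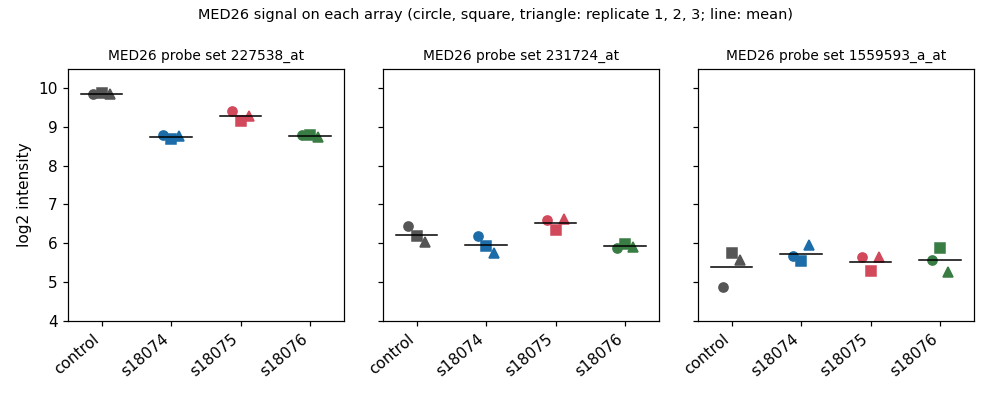
Log2 intensity of the 3 MED26 probe sets (vertical axis) on each of the 12 arrays, grouped by siRNA (horizontal axis), with the replicates as separate symbols and the group mean as a line. On the brightest probe set the 3 control arrays average 9.85 and every knockdown array lies below them, while on both dim probe sets the s18074 and s18075 arrays overlap with the controls.

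The first comparison asked what the 3 siRNAs did in common. The shared rises were led by replication-dependent histone genes, which package newly made DNA: H3C6 rose by 1.52 ± 0.08 (log2, SE, mean of the 3 siRNAs), H2BC5 by 1.40 ± 0.07 and H2BC21 by 1.35 ± 0.05. DNAI4 rose by 1.25 ± 0.14 and the linker histone gene H1-2 by 1.16 ± 0.06. TP53INP1, a stress-induced target of p53, rose by 1.19 ± 0.06, the kinase gene HIPK3 by 1.18 ± 0.06 and SLC40A1, which encodes the iron exporter ferroportin, by 1.10 ± 0.07. The strongest shared falls were in BMP2, a secreted growth factor of the TGF-beta family, at -1.33 ± 0.07, SLC7A11, the light chain of the cystine/glutamate antiporter, at -1.29 ± 0.06, and NEFM, the medium neurofilament chain, at -1.09 ± 0.05. INSIG1, which restrains cholesterol synthesis, fell by 0.97 ± 0.07, and the proto-oncogene MYC fell by 0.82 ± 0.11.

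Other large shared rises were in GPR137C (1.06 ± 0.06), BASP1 (1.05 ± 0.07), NHLRC3 (1.04 ± 0.05) and the mitotic kinase gene NEK7 (1.03 ± 0.06). Other large shared falls were in RSKR (-0.96 ± 0.09), the GABA-B receptor gene GABBR2 (-0.92 ± 0.06), LRATD2 (-0.91 ± 0.04), the adaptor gene DOK3 (-0.89 ± 0.06), the ciliary gene INVS (-0.88 ± 0.05), KRTAP19-1 (-0.86 ± 0.09) and LINC00852 (-0.83 ± 0.09). DNAI4, RSKR and LINC00852 lay among the dimmest 40% of genes. INVS took most of its fall from s18075, at -1.78 ± 0.06 against -0.47 ± 0.06 with s18074 and -0.40 ± 0.06 with s18076. The shared means also cover uneven sizes in other genes. INSIG1 gave -0.59 with s18074, -1.54 with s18075 and -0.77 with s18076. HIPK3 rose most with s18076, at 1.74, and least with s18074. GABBR2 and LINC00852 fell most with s18075, GABBR2 least with s18076 and LINC00852 least with s18074. Of these 24 genes with the largest shared changes, MED26 included, 18 had a further probe set, and for 9 of the 18 no further probe set was called in the same direction. The other probe set gave 0.21 for H3C6, not called, -0.01 for NEFM and 0.03 for BASP1. H2BC5 and H2BC21 were read from probe sets whose suffix (_x or _s) marks possible sharing between paralogs. The other H2BC5 probe set, also with _x, gave 0.83.

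In numbers, 1316 of 19775 genes were called with all 3 siRNAs in one direction, 697 higher and 619 lower (limma, Benjamini-Hochberg adjusted p under 0.05 in each). Independent lists of the same sizes would share 11.3 genes downwards and fewer upwards, and 100 simulations of unchanged groups against shared controls gave at most 0 such genes. The simulations drew noise for each gene independently, without batches, so they do not show what correlated arrays would give. Relabelled real arrays, which still hold real differences, gave up to 223 shared calls where the control arrays were never kept together. The mean of the 3 siRNAs called 4023 genes, 2011 higher and 2012 lower. Most changes were small: 14 of the genes called in the mean rose and 3 fell by at least 1 on the log2 scale. Across genes, which are not independent replicates, the fold changes of s18074 and s18075 correlated at 0.680, those of s18074 and s18076 at 0.724 and those of s18075 and s18076 at 0.610, where unchanged groups sharing the controls gave 0.501, 0.499 and 0.499. Their covariances were 0.0262, 0.0286 and 0.0265 against a simulated 0.00409, 0.00408 and 0.00407. All 3 siRNAs were compared with the same control arrays, so part of the overlap may come from sharing them. The shared count was 835 where each siRNA was fitted with the controls alone, and the mean called 2533 genes where the 9 knockdown arrays formed 1 group. Of the 1316 shared genes 868 had a further probe set. For 492 of them none was called in the same direction, and for 47 a further probe set was called in the opposite direction. In the mean of all probe sets of a gene 1068 genes were shared, 801 of them among the 1316.

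**Figure D2:**
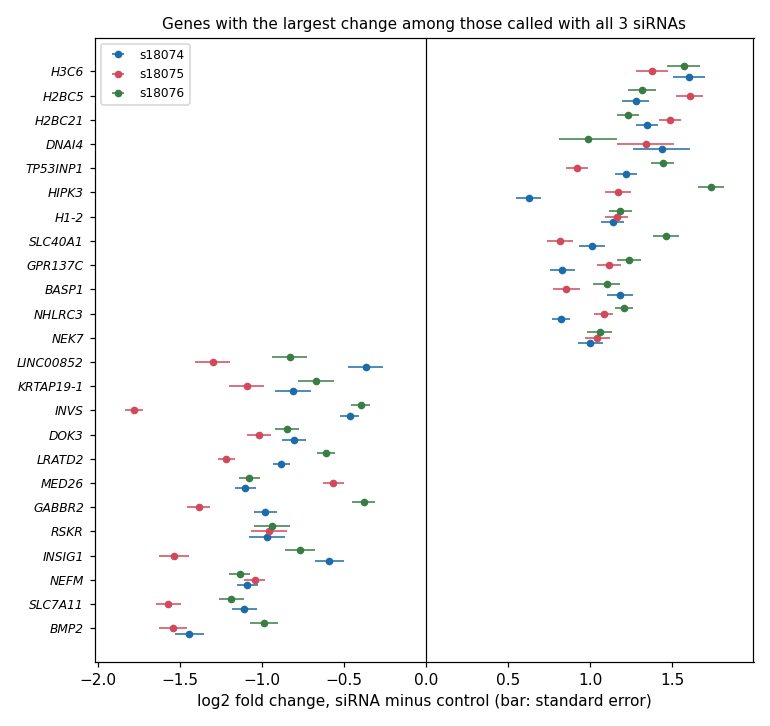
Log2 fold change against the control (horizontal axis) of the 24 genes with the largest mean change among those called with all 3 siRNAs (vertical axis), with 1 point per siRNA and bars for the standard error. H3C6 at 1.52 and BMP2 at -1.33 have the largest mean changes, and INVS lies farthest from 0 with s18075.

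The gene lists asked which known groups moved, each measured member being counted in the mean of the 3 siRNAs. Not every listed gene was measured: 7 of 18 snoRNA host genes were, 43 of 67 histone genes and 51 of 77 cytosolic ribosomal protein genes. Of 43 replication-dependent histone genes, 19 rose, 1 fell and 23 did not pass (22 rose and 1 fell when adjusted over the list alone), with a median log2 fold change of 0.18. The list shifted upwards by limma's camera (Benjamini-Hochberg adjusted p = 1.89e-09). Of 27 p53 target genes 13 rose and 0 fell (16 and 0 adjusted over the list alone; median 0.18; camera adjusted p = 1.86e-07), with the cell cycle inhibitor CDKN1A at 0.73 ± 0.05, the death receptor TNFRSF10B at 0.55 ± 0.04 and the RNA-binding protein ZMAT3 at 0.82 ± 0.16. ZMAT3 was not called with s18074, where its value was 0.27 ± 0.20. Of 7 measured snoRNA host genes, whose introns carry small nucleolar RNAs, 6 fell and all 6 did so with each siRNA (6 adjusted over the list alone; median -0.38; camera adjusted p = 9.53e-06). SNHG4 fell by 0.69 ± 0.08, EPB41L4A-AS1 by 0.44 ± 0.04, TAF1D by 0.43 ± 0.06 and ZFAS1 by 0.38 ± 0.05. Of 39 MYC and ribosome biogenesis genes 11 fell and 0 rose (11 and 0 adjusted over the list alone; median -0.11; camera adjusted p = 2.44e-05), among them NOP14 at -0.32 ± 0.05 and RIOX2 at -0.26 ± 0.05. With the preset correlation histones, p53 targets and snoRNA hosts passed with each siRNA alone, but the MYC and ribosome biogenesis list did not pass with s18075, where 4 genes fell (median -0.03, camera adjusted p = 0.167). In the mean of the 3 siRNAs these 4 lists also passed with an estimated correlation, at adjusted p = 0.0271 for the histones, 0.00546 for the p53 targets, 0.0130 for the snoRNA hosts and 0.0235 for MYC and ribosome biogenesis, but with s18076 alone the histones did not (0.0815). Without the dimmest 40% of genes too few snoRNA hosts were left for a test, and RIOX2 was not called in the mean of all its probe sets (adjusted p = 0.0619).

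In the mean of the 3 siRNAs a further 5 lists passed with the preset correlation but not with an estimated one. Of 12 genes of the microRNA machinery 7 rose and 1 fell (7 and 2 adjusted over the list alone; median 0.25; camera adjusted p = 0.00335, and adjusted p = 0.0869 with an estimated correlation), led by the Argonaute partners TNRC6A at 0.76 ± 0.04 and TNRC6C at 0.51 ± 0.08 and by AGO3 at 0.49 ± 0.05. Of 44 REST-repressed neuronal genes 12 fell and 3 rose (15 and 4 adjusted over the list alone; camera adjusted p = 0.00524, and adjusted p = 0.0997 with an estimated correlation). NEFL, the light neurofilament chain, fell by 0.80 ± 0.05 and CPLX1, a regulator of vesicle release, by 0.73 ± 0.08, whereas the kinesin gene KIF5C rose by 0.73 ± 0.05. Of 35 genes of the unfolded protein and integrated stress responses 11 fell and 3 rose (11 and 5 adjusted over the list alone; camera adjusted p = 0.00724, and adjusted p = 0.678 with an estimated correlation). With single siRNAs this list passed for s18075 alone (adjusted p = 0.000217, against 0.0745 for s18074 and 0.204 for s18076), though not with an estimated correlation (0.427). Those falls included SLC7A11 and the asparagine synthetase ASNS at -0.58 ± 0.07, and the rises included the lipoprotein receptor VLDLR at 0.57 ± 0.08. The list did not pass without control replicate 1 (adjusted p = 0.0824). Of 38 immediate-early genes 16 rose and 6 fell (19 and 6 adjusted over the list alone; camera adjusted p = 0.0175, and adjusted p = 0.0591 with an estimated correlation), with DUSP5 at 0.50 ± 0.09 and IER3 at 0.44 ± 0.04, and with TRIB1 at -0.56 ± 0.04. The immediate-early list passed with s18074 (adjusted p = 0.00932) and s18076 (0.000836), also with an estimated correlation (0.0391 and 0.0142), but not with s18075, where 7 genes rose and 8 fell (0.689). Of 32 elongation factors 7 rose and 2 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.0445, and adjusted p = 0.0886 with an estimated correlation). HEXIM1, an inhibitor of the elongation kinase P-TEFb, rose by 0.88 ± 0.06, the super elongation complex scaffold AFF4 by 0.32 ± 0.05 and RTF1 by 0.28 ± 0.05, while TCEA2 fell by 0.44 ± 0.07. With single siRNAs the elongation factors passed for s18074 alone (adjusted p = 0.0208, against 0.289 for s18075 and 0.0780 for s18076), though not with an estimated correlation (0.0606). This list did not pass without control replicate 3 (adjusted p = 0.212), nor without s18074 replicate 3, s18075 replicate 1, s18075 replicate 3 or any 1 of the s18076 arrays (adjusted p from 0.0508 to 0.0595), nor with array weights (0.0740). Without the dimmest 40% of genes the elongation factors (adjusted p = 0.0911), immediate-early genes (0.138) and REST-repressed genes (0.0562) did not pass, and in the mean of all probe sets of a gene the microRNA machinery (0.0650), AGO3 (0.188), TNRC6C (0.332) and TRIB1 (0.0518) did not.

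**Figure D3:**
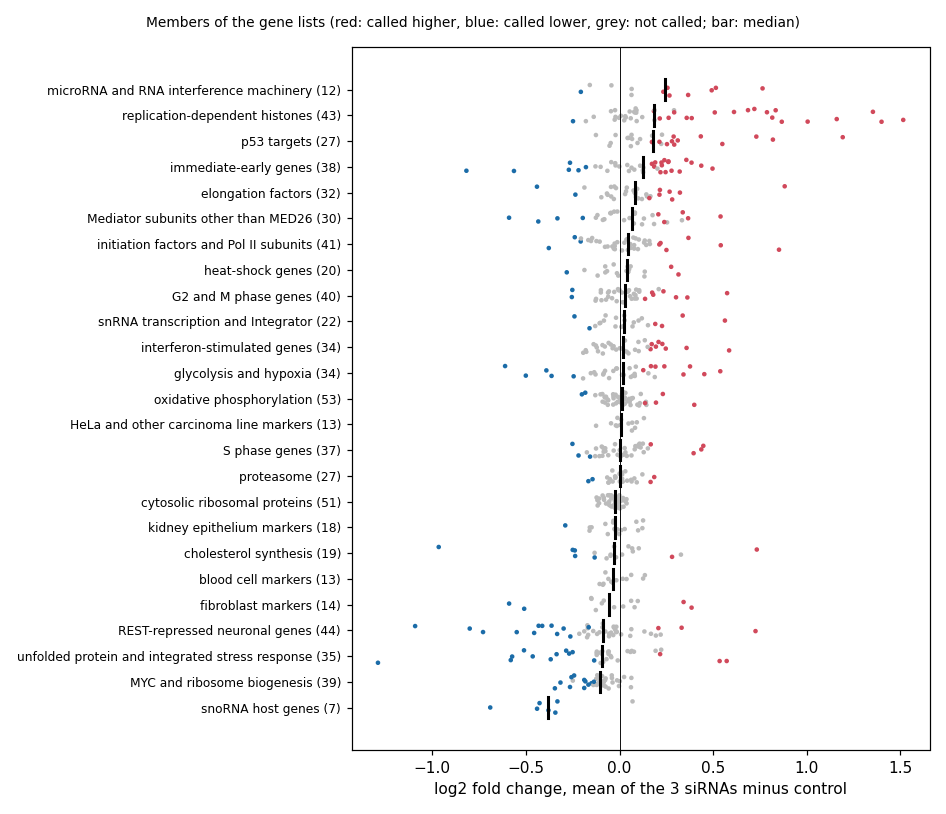
Log2 fold change of every measured member of the 25 gene lists, mean of the 3 siRNAs minus control (horizontal axis), with 1 row per list, its number of measured genes in brackets and its median as a bar. The snoRNA host genes have the lowest median, -0.38, and the microRNA machinery the highest, 0.25.

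The remaining 16 lists did not pass camera in the mean of the 3 siRNAs. With limma's fry, which tests a list without setting it against other genes, all 9 lists above passed, and so did initiation factors and polymerase subunits (adjusted p = 0.00392), interferon-stimulated genes (0.00770) and G2 and M phase genes (0.0240), each upwards. Among 30 Mediator subunits other than MED26, 5 rose and 4 fell (7 and 4 adjusted over the list alone; camera adjusted p = 0.695): MED28 rose by 0.54 ± 0.05 and MED15 by 0.37 ± 0.06, and MED11 fell by 0.59 ± 0.05 and CDK19 by 0.43 ± 0.04. Among 41 initiation factors and polymerase subunits 6 rose and 3 fell (6 and 3 adjusted over the list alone; adjusted p = 0.339), with POLR2A, the largest subunit of RNA polymerase II, up by 0.85 ± 0.05. Among 22 snRNA transcription and Integrator genes 4 rose and 2 fell (5 and 2 adjusted over the list alone; adjusted p = 0.695), with SNAPC1 at 0.56 ± 0.10. Among 34 interferon-stimulated genes 8 rose and 0 fell (9 and 1 adjusted over the list alone; adjusted p = 0.418, but 0.0358 in the mean of all probe sets of a gene), IFITM1 being highest at 0.59 ± 0.05. Among 40 G2 and M phase genes 7 rose and 2 fell (7 and 2 adjusted over the list alone; adjusted p = 0.298; with s18076 alone 9 rose, 4 fell and the list passed at 0.00812, though not with an estimated correlation, 0.188), and among 37 S phase genes 4 rose and 3 fell (6 and 3 adjusted over the list alone; adjusted p = 0.701). Among 34 glycolysis and hypoxia genes 8 rose and 5 fell (8 and 7 adjusted over the list alone; adjusted p = 0.835), with VEGFA down by 0.61 ± 0.05. Among 19 cholesterol synthesis genes 2 rose and 5 fell (3 and 5 adjusted over the list alone; adjusted p = 0.695), with STARD4 at 0.73 ± 0.07 opposite to INSIG1. Among 53 oxidative phosphorylation genes 4 rose and 2 fell (3 and 2 adjusted over the list alone), among 27 proteasome genes 2 and 2 (2 and 2), and among 20 heat-shock genes 2 and 1 (2 and 1), each with a camera adjusted p of 0.701.

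No list of markers of other cells passed. Of 14 fibroblast markers 2 rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.701), and of 18 kidney epithelium markers 1 fell, EPCAM at -0.29 ± 0.07 (1 adjusted over the list alone; adjusted p = 0.695). EPCAM did not pass without control replicate 3 (adjusted p = 0.0849). In limma, 0 of 13 blood cell markers (camera adjusted p = 0.701), 0 of 13 markers of HeLa and other carcinoma lines (0.695) and 0 of 51 cytosolic ribosomal protein genes (0.207) were called, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 these lists held 0, 1 and 3 genes. The ribosomal protein list passed camera with s18076 alone, where 4 genes fell (adjusted p = 0.00968, and 0.547 with an estimated correlation), and in the mean of all probe sets of a gene (0.0281).

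The next comparisons asked what each siRNA did alone and where the siRNAs differed. Steep falls with a single siRNA included these. With s18074 the ceramide kinase gene CERK fell by 1.59 ± 0.06 and CMTM6, which stabilises PD-L1, by 1.28 ± 0.06. With s18075 the phosphatase gene PTPN11 fell by 1.92 ± 0.06, the complex I assembly factor TIMMDC1 by a log2 fold change of -1.83 ± 0.05, the translation elongation factor EEF2 by 1.82 ± 0.06, RNASEH2C by 1.53 ± 0.08 and the dynein adaptor BICD2 by 1.49 ± 0.08. With s18076 GPKOW fell by 1.63 ± 0.06, the centrosomal gene CEP20 by 1.52 ± 0.05, SH3BGRL by 1.26 ± 0.05 and the fatty acid elongase ELOVL5 by 1.23 ± 0.06. EEF2 gave 0.02 with s18074 and -0.02 with s18076, PTPN11 gave -0.06 and -0.05, and CEP20 gave -0.01 with s18074 and -0.03 with s18075. The F test between siRNAs in limma called each of these 11 genes, with Benjamini-Hochberg adjusted p from 8.13e-10 for TIMMDC1 to 4.64e-07 for ELOVL5. These falls were read from the brightest probe set of each gene. With all probe sets of a gene averaged, PTPN11 (-0.28, limma adjusted p = 0.174) and SH3BGRL (-0.12, adjusted p = 0.156) lost their call in the mean of the 3 siRNAs. That contrast averages over all 3 siRNAs, so it does not show whether the fall with 1 siRNA holds on other probe sets.

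The single siRNAs called 2812 genes for s18074 (1319 higher, 1493 lower), 3339 for s18075 (1604 higher, 1735 lower) and 3741 for s18076 (2037 higher, 1704 lower). The largest rises of s18074 and s18075 were in H3C6, H2BC5, H2BC21 and DNAI4, and those of s18076 were in HIPK3 at 1.74 ± 0.08, H3C6, SLC40A1 and TP53INP1. The F test called 2489 genes that differed between siRNAs, and 262 of the 1316 shared genes were among them. Direct contrasts called 1259 genes between s18075 and s18074, 1010 between s18076 and s18074 and 2177 between s18076 and s18075, and 150 genes were called in opposite directions by any 2 siRNAs. At a log2 fold change of at least 1 the counts were 19, 54 and 49 for s18074, s18075 and s18076, and with replicate 1 against replicates 2 and 3 as a block the F test called 3770 genes.

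**Figure D4:**
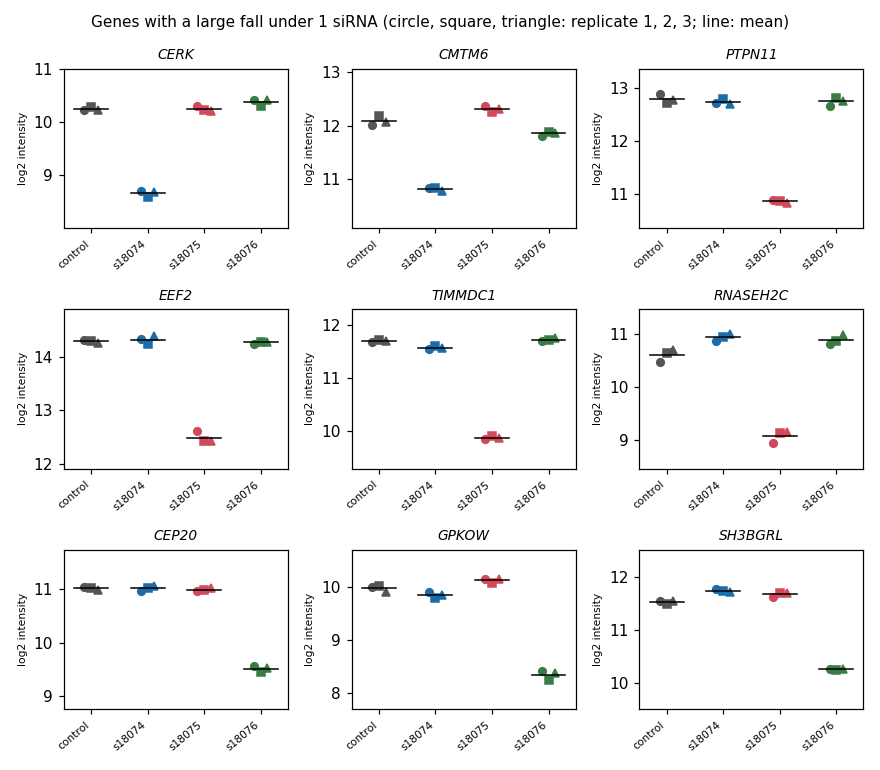
Log2 intensity (vertical axes, each spanning the same range) of 9 genes with a large fall under 1 siRNA, on each array by group (horizontal axis), with replicates as separate symbols and group means as lines. PTPN11, EEF2, TIMMDC1 and RNASEH2C are low in the 3 s18075 arrays, CERK and CMTM6 in the 3 s18074 arrays, and CEP20, GPKOW and SH3BGRL in the 3 s18076 arrays.

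The replicate 1 arrays stood apart from the others in all 4 groups. The log2 ratio of 3' to 5' signal of the beta-actin control probe sets lay between 0.42 and 0.62 on the replicate 1 arrays and between 1.89 and 2.69 on replicates 2 and 3, while the means of the groups, over actin and GAPDH, were 0.96 for the control and 0.86, 0.93 and 0.95 for s18074, s18075 and s18076. Between these batches 2311 genes differed (limma, 1210 higher and 1101 lower in replicate 1). Each batch held all 4 groups, and the effects of MED26 siRNAs in replicate 1 correlated with those in replicates 2 and 3 at 0.705 across genes, although the batches share no array. The median fold change in replicate 1, then in replicates 2 and 3, was 0.21 and 0.18 for histones, 0.19 and 0.19 for p53 targets, -0.38 and -0.40 for snoRNA hosts, and -0.11 and -0.11 for MYC and ribosome biogenesis. For the microRNA machinery these medians were 0.24 and 0.23, for immediate-early genes 0.14 and 0.11, for elongation factors 0.04 and 0.07, for REST-repressed genes -0.06 and -0.07 and for the stress responses -0.13 and -0.07. With the batch as a block all 9 lists passed, the elongation factors at a camera adjusted p of 0.0350, and the counts were 4047, 4724 and 5022 genes for the single siRNAs, 5309 for their mean and 1970 shared. On replicates 2 and 3 alone they were 2112, 2783 and 3119, then 3456 and 974.

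**Figure D5:**
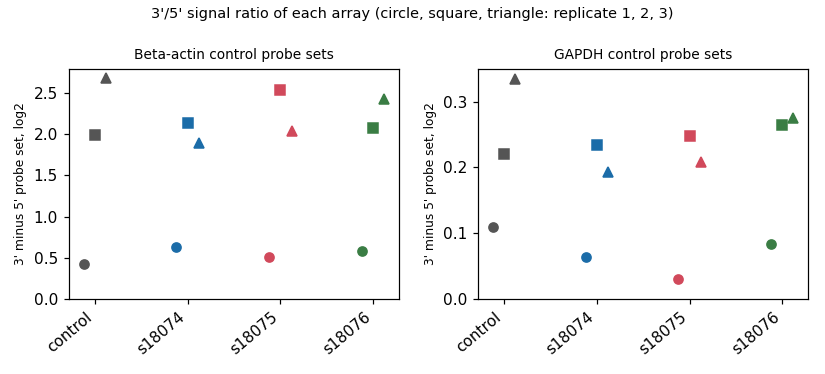
Log2 ratio of the 3' to the 5' probe set (vertical axes) of the beta-actin and GAPDH control transcripts on each array, by group (horizontal axis), with replicates as separate symbols. The replicate 1 arrays lie lowest in every group, for actin between 0.42 and 0.62.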

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

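Here 4 tests were chosen only after the result was seen: the count of called histone probe sets, the direction of genes set apart by 1 siRNA, the slope on arrays that neither side shares, and the estimated correlation for lists between siRNAs. The relabelling that never keeps the real control arrays together was also added after the planned one had been seen.

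The siRNAs differed at 2489 genes by the F test. The widest ranges of log2 fold change over the siRNAs were 1.88 for PTPN11, 1.86 for RNASEH2C, 1.85 for TIMMDC1, 1.84 for BICD2, 1.84 for EEF2 and 1.77 for GPKOW. A further 42 named genes were called by that test, and 10 differences between siRNAs in the shift of a gene list passed camera with the preset correlation, 0 with an estimated one. Among probe sets with no or several gene names, which no comparison used, 274 of 13522 were called with all 3 siRNAs in one direction, 116 higher and 158 lower.

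MED26 was higher with s18075 than with s18074 by 0.54 and lower with s18076 than with s18075 by a difference of -0.51, yet s18075 called 3339 genes, more than s18074 (2812) though fewer than s18076 (3741). Effects in proportion to the fall in MED26 mRNA, read from its brightest probe set, are argued against. Over 1911 genes called with s18074 and s18076 in one direction, the s18075 effect was 0.818 of the mean of the others. Its bootstrap 95% interval, 0.795 to 0.842, lay above the MED26 ratio of 0.520. The interval of this slope was taken over genes, so it does not measure the spread between arrays. The MED26 ratio was given no interval. Shared control arrays raise that slope, but with each side on its own arrays the slopes were 0.744 to 0.807, above the MED26 ratios of 0.386 to 0.668, and s18074 gave 0.772 to 0.779 where its MED26 ratios were 1.21 to 1.51. Additional changes by s18075 alone passed their test, since 67.7% (exact interval 64.2% to 71.1%) of the 734 genes at which it stood apart lay farther from the control with it. The selection favours this result, because a gene that the other siRNAs left unchanged can only lie farther with s18075. Of the genes at which s18075 stood apart, 357 were called with neither other siRNA. The share was also 71.7% of 597 for s18076, which had no weaker knockdown, and 54.3% of 245 for s18074 (47.8% to 60.6%). For both reasons this test does not single out s18075. Unintended silencing by each siRNA, untested here by sequence, is a hypothesis that would give an excess of falls among the genes farther from the control. Of these genes, 82.0% of 133 fell with s18074 and 80.5% of 497 with s18075. The lowest share was 61.0% of 428 for s18076 (exact interval 56.2% to 65.6%), where 47.0% of the shared calls were falls. The exact intervals count genes as independent, which they are not.

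The rise of histone genes has other candidate sources, biological and technical. A larger share of cells in S phase was tested on the 37 S phase genes, whose median log2 fold change was 0.00492. Its bootstrap interval over genes, -0.08 to 0.08, lay below the 0.1 set in advance, which argues against a shift of that size. The interval does not measure the spread between arrays. These genes are also correlated (0.129, estimated), so it may be too narrow, and a smaller shift is not excluded. Signal shared between histone paralogs stayed open in the planned test: the 36 histone probe sets with a plain _at name had a median log2 fold change of 0.09 (0.0898, interval 0.05 to 0.22), which spans 0.1, against 0.66 for the 12 with a suffix (_s or _x) that marks possible sharing. In the count chosen afterwards, 10 of the 36 (27.8%, exact interval 14.2% to 45.2%) were called higher, against 5.83% of all plain _at probe sets, which argues against sharing as the whole source but does not settle the planned test. More transcripts with a poly(A) tail, which most histone mRNAs lack, may also raise these signals, and this was not tested.

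The replicate 1 arrays stood apart in all groups. A difference in 3' bias was supported, since their mean 3'/5' log2 ratio over actin and GAPDH was lower by a difference of -0.93 (-1.04 to -0.77 over the 4 groups), where replicates 2 and 3 of a group differed by at most 0.41. This may reflect RNA quality, another labelling run, or the culture format, since the protocol names both 6-well plates and 10 cm dishes, which the labels do not separate, and no biological explanation was tested. Each group holds 1 such array, so the groups are balanced over it.

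Chance groupings of the arrays were counted for each result. For the mean of the 3 siRNAs, 1 of 100 relabellings, the real one, gave as many as its 4023 genes (highest other 2459), and for the shared calls 1 of 100 gave 1316 (highest other 809). Both highest values came from the 1 relabelling that kept the 3 control arrays together. For the gene lists 2 of 100 relabellings gave 9 passing lists, the real one and that same relabelling. With the control arrays never kept together, 1 of 100 relabellings gave as many in each case, with a highest other of 1071 genes, 223 shared calls and 8 lists. The 8 lists, close to the real 9, came from a split with 2 controls and an s18075 array as the control group. Such a split keeps much of the real contrast, so it does not show how many lists an arbitrary grouping gives. For the F test 1 of 100 regroupings of the 9 knockdown arrays gave 2489 genes (highest other 702). For s18074, s18075 and s18076 alone 10 splits are too few for a share under 0.05: 1 split of each gave as many as the real 1883, 2487 and 2568 genes of the fit on 6 arrays, and the highest other gave 0.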

How the results depend on the processing

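The batch block, the fit on replicates 2 and 3 and the estimated correlation for lists between siRNAs were chosen after seeing the data. MED26 kept its direction and call under every alternative run on it, and the correlations between siRNAs moved by less than 0.1. At an adjusted p under 0.01 the counts were 1440 (s18074), 1896 (s18075), 2190 (s18076), 2402 (mean), 650 (shared) and 1304 (F test), and at a log2 fold change of at least 1 they were 19, 54, 49, 17, 6 and 69, both stricter by construction. Tests of all probe sets, which are more numerous, called 5428 with s18075, 5892 with s18076 and 6833 in the mean. Fitting each siRNA with the controls alone left 835 shared genes and taking the 9 knockdown arrays as 1 group left 2533 in the mean, while the batch block raised the F test to 3770; the cause was not tested. Of 9 lists 5 passed without the dimmest 40% of genes (elongation factors, immediate-early genes and REST-repressed genes did not, and too few snoRNA hosts were left for a test) and 4 with an estimated correlation; of 10 list differences between siRNAs 0 did.

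With 1 array left out, the counts ran from 1890 to 2930 (s18074), 2336 to 3506 (s18075), 2833 to 3673 (s18076), 3014 to 4092 (mean), 997 to 1299 (shared) and 1721 to 2630 (F test), and 8 to 9 lists passed. Of the values of named genes under the alternatives 2400 kept their side of the threshold, 43 lost the call and 5 gained it, and of those of lists, without the estimated correlation and fry (12 lists passed), 508, 13 and 2. IRF7, PSMA5, LYAR, INTS5 and DNAJB4 were among those that lost it without 1 array. No result reversed.

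Replicate 1 arrays correlated with each other (0.326 to 0.439), but numbers 2 and 3 were not told apart (same number -0.0240 to 0.248, different -0.00257 to 0.315), so the numbers were not used as pairs. With the replicate block the counts were 3697, 4362 and 4680 for the single siRNAs, 5019 (mean), 1796 (shared) and 3377 (F test), and 9 lists passed. Dim probe sets, such as 2 of the 3 for MED26, limit what can be seen.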

Other observations

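The estimated correlation was tried here only after the result was seen. Differences between siRNAs in how far they moved gene groups passed only with the preset correlation: of 75 tests 10 passed with it and 0 with an estimated one (smallest adjusted p = 0.126), so the following are leads. G2 and M phase genes were higher with s18076 than with s18074 by a median log2 difference of 0.13 (camera, Benjamini-Hochberg adjusted p = 3.81e-05 over 75 tests), and cytosolic ribosomal protein genes were lower with s18076 than with s18074 by a median of -0.04 (adjusted p = 0.00444). MYC and ribosome biogenesis genes were lower with s18076 than with s18075 (median -0.11, adjusted p = 0.000329) and than with s18074 (-0.04, 0.0389), and snoRNA host genes were lower with s18076 than with s18074 (-0.16, 0.0378). Histone genes were lower with s18076 than with s18075 (-0.08, 0.00459). Genes of the unfolded protein and integrated stress responses were lower with s18075 than with s18074 (-0.08, 0.00444) and higher with s18076 than with s18075 (0.04, 0.00839), as were immediate-early genes (-0.02, 0.0413, and 0.11, 0.00188).

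Single members went against their group or stood out from it. In the G2 and M phase list the cytokinesis genes ANLN (0.57 ± 0.06, SE) and PRC1 (0.36 ± 0.04) rose while the mitotic cyclin CCNB1 fell by 0.26 ± 0.05, each with all 3 siRNAs. Of the hypoxia genes NDRG1 fell by 0.50 ± 0.06 and ADM rose by 0.45 ± 0.05. The fibroblast genes LUM (-0.59 ± 0.06) and COL3A1 (-0.51 ± 0.11) fell, both among the dimmest 40%, and FBN1 rose with s18074 (0.53 ± 0.05) and s18075 (0.51 ± 0.05) but gave -0.02 ± 0.05 with s18076 (F test adjusted p = 1.76e-05).

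A scan of 140 families of gene symbols with the same stem and at least 15 genes found 0 that passed camera (smallest adjusted p = 0.308), with 11 at an unadjusted p under 0.05.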
